A study of Mus musculus with 4 samples.

How the data were processed

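RNA-seq was run on total RNA from 4 samples of MIN6 cells, 2 labelled control and 2 labelled TLX overexpression, per the labels. Per the labels' protocols, the cells were kept in medium with 25 mM glucose and 15% serum, and libraries followed the usual Illumina preparation. Per the submitters' processing notes, TopHat2 2.0.13 and the mouse genome build mm9 were used. The counting program, the annotation, the treatment of reads with several matches and the use of strand are not given in the sources used here.

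The authors deposited a single table of raw read counts, whole numbers per feature and library with no normalization, beside a feature length, per the file headers. It has 56826 rows, of which 23473 carry a gene name and 33353 (58.7%) the name of a FANTOM3 cDNA clone. Clone rows took 24.3% and 25.1% of the counts in control replicates 1 and 2, and 23.3% and 25.1% in TLX replicates 1 and 2. Of 913 clone rows with at least 1000 counts over the 4 libraries, 17 had the same 4 counts as a gene row, against 0 after clone counts were raised or lowered by 10%, so some clone rows repeat counts of genes. How many more do is not known. Within 2% of a gene row in every library lay 139 (15.2%), and 774 did not. After the same shifts 92 (10.1%) and 85 (9.31%) did, so a match within 2% can be coincidence. These comparisons were chosen after the data were seen. Clone rows were left out of library sizes and tests, and the deposited totals, which count some reads more than once, are no exact depth. The ribosomal RNA row Rn45s took 14.2% and 14.3% of gene row counts in control and 12.2% and 16.7% in TLX. There are 27 rows with a gene name turned into a date by a spreadsheet; 16 were tested, 1 was called and none is named. Gene names were used as the table gives them, and 99.4% of gene rows match a symbol or synonym in the reference name tables (RefSeq of GRCm38.p6 and GENCODE). That build differs from mm9, so no coordinates are given.

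Each library was matched to its group and replicate number by its labels. Pairs of libraries were compared gene by gene by a chi-square of their counts over genes with at least 50 counts. The median was 1.07 for the control pair and 0.718 for the TLX pair, against 0.455 for sampling noise alone and 1.99 to 2.28 between groups, so no pair was taken for the same library deposited 2 times.

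Counts of gene rows were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest) for TLX against control, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment over 11024 genes at 0.05. The common biological coefficient of variation was 5.24%. Levels are CPM on TMM-scaled library sizes with the SD over 2 libraries. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Before the data were examined, 41 gene lists were fixed. Those with at least 5 tested members were tested with limma's camera on log-CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over 33 lists, beside camera with an estimated correlation and fry. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

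The genes to name were set by a rule before the data were examined. It took Nr2e1, the 12 largest rises and 12 largest falls by log2 fold change among called genes that average at least 5 CPM with groups that do not overlap, leaving out gene models without a name, up to 4 members of smallest p from each list, and 18 genes of beta cell identity, TLX biology and the cell cycle. Not all genes the rule allows are named. Any other gene is said to have been chosen after its values were seen.

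The test was tried on simulated counts with the means and library sizes of this comparison over 11024 genes. It called 18 of 50 genes changed 1.25-fold, 36 of 50 at 1.5-fold, 44 of 50 at 2-fold and 50 of 50 at 4-fold, and 11 of 10794 unchanged genes. A simulated list shifted 1.32-fold was called by camera with the preset correlation and not with an estimated one. Of 40 unchanged lists 0 were called with either. Genes were simulated independently of each other, so these list results do not cover lists whose genes vary together.

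Alternatives fixed before the data were examined were DESeq2's size factors, total counts without normalization factors, no filter on low counts, a filter of 10 CPM on average, DESeq2's Wald test, limma-voom, the replicate number as a block, glmTreat against a fold of 1.5 and leaving out each library in turn. Ranges over the alternatives in the report leave out the block. Added after the data were seen were fits on all feature rows and fits without Rn45s and Lars2.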

Results

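RNA-seq read counts per gene were analysed for 4 libraries labelled as MIN6 cells, a mouse insulinoma line grown as a model of the insulin-producing beta cell. Control cells gave 2 libraries, and cells that stably overexpress TLX, an orphan nuclear receptor encoded by Nr2e1, gave the other 2. The question was which transcripts differ when TLX is overexpressed. The table held 11138932 and 13066536 counts for control replicates 1 and 2, and 11067279 and 10865462 for TLX replicates 1 and 2. Gene rows took 8435976 and 9788646 of these counts in control and 8490145 and 8136185 in TLX. Of 23473 gene rows, 7738 were at 0 in all 4 libraries and 11024 had enough counts to be tested. A count of 0 in a library allows a level of up to 0.302 to 0.379 CPM (3 counts, counting error only).

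Nr2e1 was counted 8 and 10 times in the control libraries and 338 and 281 times in the TLX libraries. Its level was 0.983 ± 0.034 CPM in control and 37.3 ± 2.6 CPM in TLX (SD, n = 2), a log2 fold change of 5.22 with an SE of 0.20 (37.4-fold; edgeR adjusted p = 3.18e-14). The direction and the call held under each alternative run for this gene, which leaves out the test against a 1.5-fold change.

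Among all genes tested, 859 were higher and 997 were lower with TLX (edgeR quasi-likelihood test, adjusted p under 0.05), which is 16.8% of the genes tested. Most changes were small, with a median of 1.36-fold over the 1856 genes called. At least 1.5-fold rises numbered 156 and falls of that size 372; at least 2-fold, they numbered 37 and 115. These counts include Nr2e1 itself. In all 1856 called genes both TLX libraries lay on the same side of both control libraries, as did 57.1% of all tested genes, against 33.3% by chance for 2 libraries against 2.

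**Figure D1:**
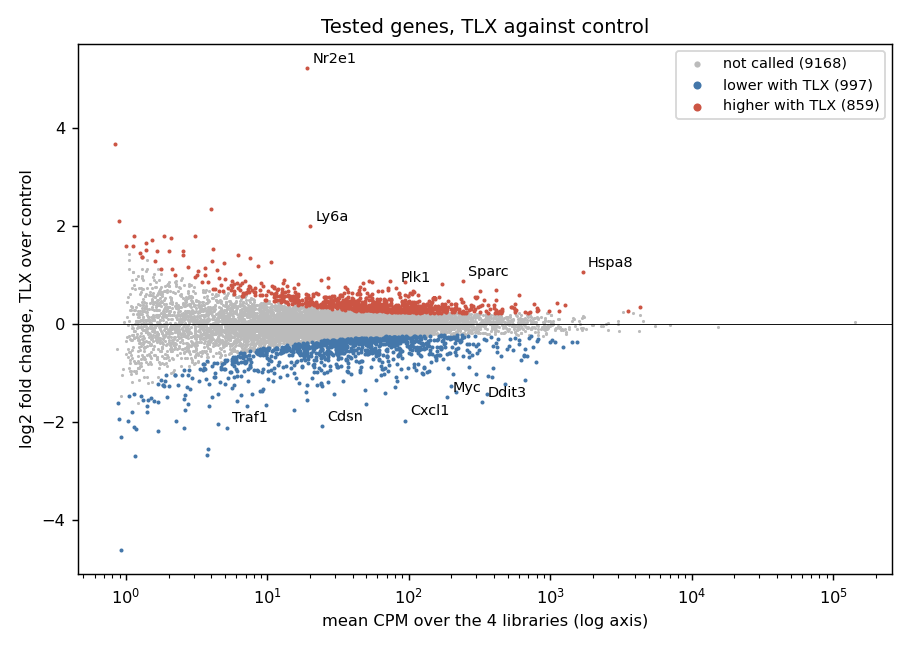
Log2 fold change of TLX over control (vertical axis) against mean CPM over the 4 libraries (horizontal axis, log scale) for the 11024 tested genes, each point a gene, coloured by whether it was higher (859), lower (997) or not called in the edgeR test. Nr2e1 stands apart at 5.22, and the remaining named genes lie between -2.11 (Traf1) and 1.99 (Ly6a).

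The largest rises after Nr2e1 among genes averaging at least 5 CPM included genes of a surface antigen, a chaperone and a secreted peptide. Ly6a, the surface antigen Sca-1, rose from 8.10 ± 0.06 to 32.2 ± 6.6 CPM (log2 fold change 1.99, SE 0.15, adjusted p = 3.54e-09). Hspa8, the constitutive Hsc70 chaperone, was by far the most abundant of them and rose 2.09-fold, from 1096 ± 49 to 2289 ± 59 CPM (SD, n = 2; adjusted p = 8.58e-09). Apln, which encodes the peptide apelin, rose 2.40-fold, and the orphan receptor gene Gprc5b rose 2.54-fold. Fam46b (2.66-fold), Tmem179 (2.28-fold), Adam33 (2.03-fold), Cmpk2 (1.93-fold), Tesk2 (1.90-fold), Olfm1 (1.88-fold) and Them6 (1.87-fold) completed the group, with adjusted p between 5.17e-06 and 0.00511. Tesk2 did not pass in DESeq2 (adjusted p = 0.111; 0.000707 to 0.111 over the alternatives).

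The largest falls included genes of inflammatory signalling, stress and growth control. Cxcl1, a neutrophil-attracting chemokine, fell from 149.8 ± 0.7 to 38.2 ± 2.3 CPM (log2 fold change -1.97, SE 0.09, adjusted p = 3.97e-13). Ddit3, which encodes the stress factor CHOP, fell from 497 ± 23 to 165 ± 13 CPM (log2 fold change -1.59, SE 0.08, adjusted p = 4.65e-12). Myc fell from 277 ± 5 to 98.4 ± 5.1 CPM (log2 fold change -1.49, SE 0.08, adjusted p = 6.61e-12). Traf1, an adaptor of tumour necrosis factor receptors, showed a log2 fold change of -2.11, Cdsn of -2.08, the lipoprotein lipase inhibitor Angptl4 of -1.75, the growth factor Areg of -1.64 and Car6 of -1.63. Atp2a3, a calcium pump of the endoplasmic reticulum, had -1.67, Slc2a6 -1.57, Creb5 -1.54 and the glutathione transferase gene Gsto2 -1.44. Without TLX replicate 2 the value of Atp2a3 was -2.47, and without TLX replicate 1 that of Slc2a6 was -2.17. Atp2a3 did not pass in DESeq2 (adjusted p = 0.0762; 8.55e-15 to 0.0762 over the alternatives); the other genes of this paragraph passed in both tools.

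**Figure D2:**
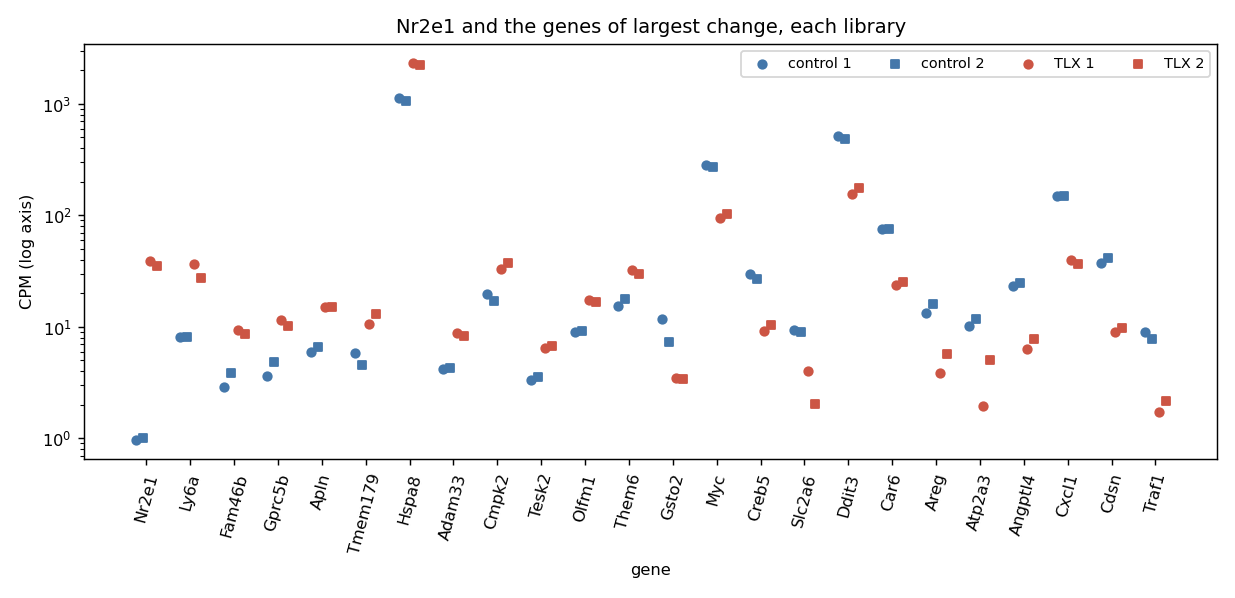
CPM of each library (vertical axis, log scale; blue control, red TLX, circles replicate 1, squares replicate 2) for Nr2e1 and the genes with the largest rises and falls among called genes averaging at least 5 CPM. For every gene shown both TLX points lie on 1 side of both control points, as the rule that chose these genes required. An example is Ly6a, with 36.9 and 27.5 against 8.15 and 8.06 CPM.

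Most transcripts of the beta cell lists were low or at 0 in all 4 libraries, control and TLX alike. Ins1 was at 9.0 ± 0.5 CPM in control and 10.1 ± 1.8 CPM in TLX, and Ins2 at 4.7 ± 1.0 and 5.0 ± 1.8 CPM (SD, n = 2). The beta cell transcription factor genes Pdx1 (4.11 ± 0.12 and 3.99 ± 0.25 CPM) and Mafa (1.64 ± 0.05 and 2.18 ± 0.30 CPM) were also low, and none of these 4 genes passed the test (adjusted p of 0.548, 0.863, 0.932 and 0.475). Nkx6-1, Neurod1, the glucose transporter gene Slc2a2, the channel genes Abcc8 and Kcnj11 and the prohormone convertase genes Pcsk1 and Pcsk2 had 0 counts in every library. Of 25 beta cell function genes 14 were at 0 in all libraries and 3 averaged at least 5 CPM, the highest being Gng12 at 73.2 CPM. Of 23 beta cell transcription factors 13 were at 0 and 4 averaged at least 5 CPM, with Foxa1 at 14.2 and Glis3 at 6.56 CPM. Of the function genes 4 were tested, and 0 rose or fell (0 and 0 adjusted over the list alone; 0 at an unadjusted p under 0.05 in edgeR and 0 in DESeq2). The same held for the 7 tested transcription factors, with 0 and 0 over all genes, 0 and 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 in edgeR and 0 in DESeq2 (camera adjusted p = 0.623). DESeq2 gave no adjusted p for 855 of the genes tested, so a 0 there can include members it did not assess.

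Some mesenchymal transcripts were abundant in the same libraries, and others were at or near 0. Col1a2, a chain of type I collagen, averaged 3523 CPM over the 4 libraries, Vim 1716, S100a4 1589, Fn1 790 and Sparc 240. Of the 20 genes of the mesenchymal and fibroblast list 9 had too few counts to be tested, among them Dcn at 0.147, Thy1 at 0.060, Acta2 at 0.055 and Lum at 0 CPM. Col1a2, Vim, S100a4, Dcn, Thy1, Acta2 and Lum were chosen after their values were seen, as were Iapp and Chga, which stood at 0 counts. Of 11 tested mesenchymal and fibroblast genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.824). Sparc rose from 170 ± 7 to 310 ± 4 CPM (adjusted p = 2.21e-08). Fn1, which encodes fibronectin, fell from 994 ± 35 to 586 ± 29 CPM (adjusted p = 4.34e-07), and the transcription factor gene Snai2 fell from 28.4 ± 3.4 to 14.6 ± 0.6 CPM (adjusted p = 1.05e-05). Col1a2, also counted among those that rose (log2 fold change 0.28, adjusted p = 0.0434), did not pass when any single library was left out (0.0707 to 0.22; 0.00355 to 0.22 over the alternatives).

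**Figure D3:**
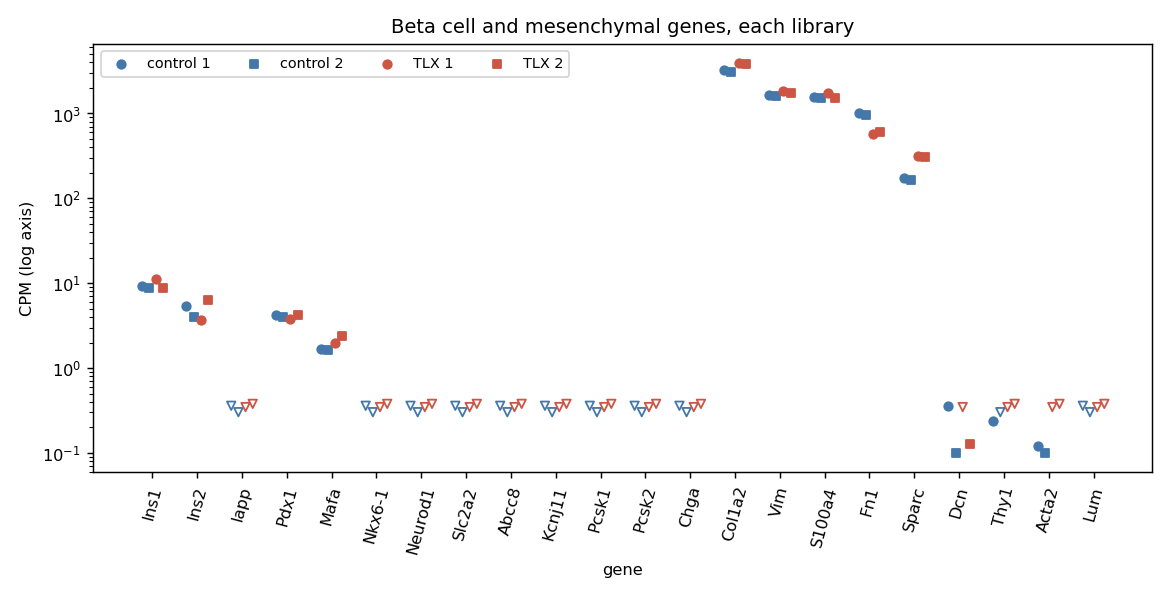
CPM of each library (vertical axis, log scale; blue control, red TLX, circles replicate 1, squares replicate 2) for beta cell genes on the left and mesenchymal genes on the right; open triangles mark libraries with 0 counts, drawn at the level that 3 counts would give, so that points of 1 or 2 counts can lie below them. Ins1 averaged 9.54 CPM over the 4 libraries, Col1a2 3523 and Dcn 0.147.

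Cell cycle genes were higher with TLX. Of 36 tested genes of G2/M and mitosis, 25 rose, 0 fell and 11 did not pass, and 31 rose adjusted over the list alone (camera adjusted p = 1.58e-12; adjusted p = 0.463 with an estimated correlation). All 36 had a positive log2 fold change. The mitotic kinase gene Plk1 rose from 60.2 ± 1.7 to 101 ± 5 CPM (adjusted p = 1.47e-06), and Foxm1, a transcription factor of mitotic genes, from 193 ± 5 to 276 ± 4 CPM (adjusted p = 3.48e-05). Cenpf and Top2a rose by 0.76 and 0.56 on the log2 scale. Of 40 genes of G1/S and DNA replication 12 rose, among them Rrm2 (log2 fold change 0.63) and the helicase gene Mcm6 (0.44), 1 fell and 27 did not pass, with 15 and 1 adjusted over the list alone (camera adjusted p = 3.53e-05; adjusted p = 0.513 with an estimated correlation). Of 21 cyclins, cyclin-dependent kinases and their inhibitors 8 rose, including Ccne1 (0.64), Ccnb1 (0.50) and Ccnd3 (0.45), and 1 fell, with 12 and 1 adjusted over the list alone (camera adjusted p = 4.06e-05; adjusted p = 0.549 with an estimated correlation). The gene that fell was Cdkn1a, an inhibitor of cyclin-dependent kinases, from 666 ± 13 to 532 ± 18 CPM (adjusted p = 0.00517, and 0.0548 and 0.159 without TLX replicates 1 and 2; 0.000503 to 0.159 over the alternatives). Of 18 E2F and Rb family genes 4 rose and 0 fell, with 4 and 0 adjusted over the list alone (camera adjusted p = 0.00404; adjusted p = 0.775 with an estimated correlation, and 0.0748 without control replicate 1; 0.000956 to 0.775 over the alternatives). E2f7 had the largest of these rises, at 0.69, and E2f1 rose by 0.37 (adjusted p = 0.0779 without TLX replicate 2; 0.000763 to 0.0779 over the alternatives). Other cell cycle genes chosen before the data were examined did not pass: E2f6 had a log2 fold change of 0.41, Ccnd1 of 0.22, Mki67 of 0.19 and Ccnd2 of 0.15 (adjusted p of 0.0874, 0.0557, 0.24 and 0.216). Ccnd1 passed in DESeq2 and limma-voom (adjusted p of 0.0356 and 0.0337), and Mki67 and Ccnd2 passed without control replicate 2 (0.016 and 0.0454). Over the alternatives adjusted p ranged from 0.0756 to 0.461 for E2f6, 0.0337 to 0.345 for Ccnd1, 0.016 to 1.0 for Mki67 and 0.0454 to 0.649 for Ccnd2. The value of Mki67 without TLX replicate 2 was -0.00019.

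Immediate early genes, which respond within minutes to growth factors and stress, were lower with TLX. Of 20 tested, 0 rose, 15 fell and 5 did not pass, with 0 and 17 adjusted over the list alone (camera adjusted p = 1.58e-12; adjusted p = 0.463 with an estimated correlation). Next to Myc, the phosphatase gene Dusp5 had a log2 fold change of -1.42, Klf6 of -1.01 and Egr1 of -0.87, with Egr1 falling from 345 ± 15 to 189 ± 3 CPM (adjusted p = 2.39e-08).

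Targets of the stress factor ATF4, which include genes of amino acid transport and synthesis, were also lower. Of 24 tested, 0 rose, 16 fell and 8 did not pass, with 0 and 18 adjusted over the list alone (camera adjusted p = 5.71e-09; adjusted p = 0.513 with an estimated correlation). Trib3 fell from 399 ± 10 to 197 ± 6 CPM, Nupr1 from 183 ± 4 to 94.4 ± 0.5 CPM and the arginine transporter gene Slc7a1 from 542 ± 6 to 347 ± 4 CPM (adjusted p between 1.9e-09 and 2.02e-06). Of 28 genes of the wider unfolded protein response 8 rose and 9 fell, with 12 and 10 adjusted over the list alone (camera adjusted p = 0.713). Those that fell included Ppp1r15a (-1.07), Wfs1 (-1.05), Ddit3 and Trib3. Of 23 p53 targets 0 rose and 6 fell, with 0 and 7 adjusted over the list alone (camera adjusted p = 0.185, and 0.0226 when genes under 10 CPM on average were left out; 0.0226 to 0.775 over the alternatives). Gadd45a fell from 313 ± 27 to 120 ± 8 CPM (adjusted p = 6.28e-11), and Plk2 from 529 ± 12 to 251 ± 14 CPM (adjusted p = 1.26e-09).

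Interferon response genes were higher with TLX. Of 28 tested, 15 rose, 2 fell and 11 did not pass, with 17 and 2 adjusted over the list alone (camera adjusted p = 3.53e-05; adjusted p = 0.463 with an estimated correlation). Oasl2 rose from 125 ± 1 to 219 ± 11 CPM (adjusted p = 9.45e-08), and the guanylate-binding protein gene Gbp3 and the transcription factor gene Irf7 had log2 fold changes of 0.73 and 0.55. Oasl1, of the same family as Oasl2, fell from 364.9 ± 0.4 to 244 ± 3 CPM (adjusted p = 6.86e-06).

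**Figure D4:**
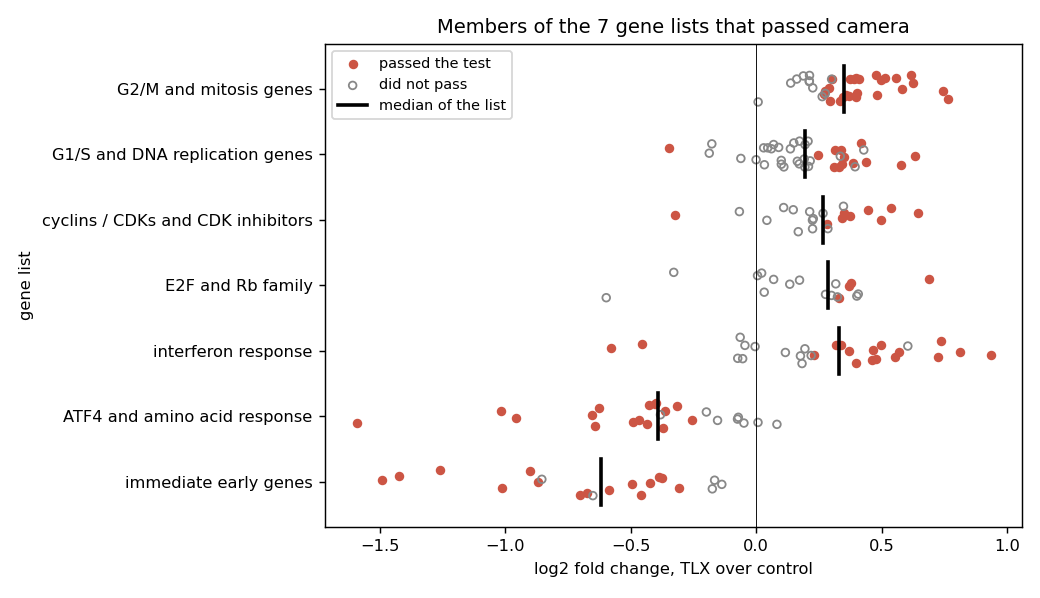
Log2 fold change of TLX over control (horizontal axis) for the tested members of the 7 gene lists that passed camera with a preset correlation (vertical axis); filled points passed the edgeR test, open points did not, and black bars mark the list medians. Medians were -0.62 for immediate early genes, -0.39 for ATF4 targets and 0.35 for G2/M and mitosis genes.

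Genes reported elsewhere as TLX targets or partners showed no common direction: of 11 tested 1 rose and 2 fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.713). Vegfa fell from 151 ± 10 to 106 ± 4 CPM (adjusted p = 9.11e-05). Of 24 nuclear receptor genes 3 rose, Nr2e1 included, and 4 fell, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.725); Nr2c1 fell by 0.87 on the log2 scale (adjusted p = 3.04e-05).

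Metabolic and redox lists held changes in both directions. Of 22 antioxidant genes 8 rose and 4 fell, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.288). The metallothionein gene Mt2 fell from 667 ± 92 to 288 ± 8 CPM. Gclm, a subunit of the enzyme that limits glutathione synthesis, rose from 67.4 ± 2.0 to 103 ± 6 CPM (adjusted p of 1.41e-09 for Mt2 and 1.66e-05 for Gclm). Of 17 hypoxia response genes 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.713), among them Ndrg1, from 904 ± 14 to 412 ± 6 CPM (adjusted p = 5.77e-10). Of 19 glycolysis genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.374, and 0.0362 without control replicate 1; 0.0362 to 0.994 over the alternatives), with Eno2 at -0.76. Of 32 genes of the TCA cycle and mitochondrial shuttles 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.607), with Got1 at -0.63. Of 26 genes of fatty acid synthesis and oxidation 5 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.455), and the lipid droplet genes Dgat2 and Plin2 had log2 fold changes of -1.15 and -0.63. Of 24 cholesterol synthesis genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.43). None of 43 nuclear genes of oxidative phosphorylation was called, with 0 and 0 adjusted over the list alone and 0 in DESeq2, though 5 had an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.356). Of 49 cytosolic ribosomal protein genes 0 rose and 1 fell, Rpl10a (-0.23, with adjusted p of 0.148 to 0.377 without control replicate 2 or either TLX replicate and 0.0127 to 0.377 over the alternatives), with 0 and 0 adjusted over the list alone (camera adjusted p = 0.288, but 0.0205 without control replicate 2 and 0.0423 without TLX replicate 1; 0.0205 to 0.861 over the alternatives).

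The remaining lists did not pass camera. Extracellular matrix and adhesion genes came closest, with 6 of 24 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0513, and 0.0498 without Rn45s and Lars2; 0.0498 to 0.644 over the alternatives), and Cdh2, which encodes N-cadherin, rose from 54.1 ± 1.7 to 87.3 ± 3.6 CPM (adjusted p = 5.21e-06). Counts of genes that rose and fell were 4 and 1 of 14 for ion channels and calcium handling (6 and 2 adjusted over the list alone; camera adjusted p = 0.156), 3 and 1 of 15 for Wnt signalling (3 and 1; 0.367), 2 and 0 of 23 for insulin and IGF signalling (1 and 0; 0.356) and 3 and 1 of 14 for antigen presentation (4 and 1; 0.662). They were 1 and 2 of 26 for apoptosis regulators (1 and 2; 0.537), 0 and 3 of 14 for the circadian clock (0 and 4; 0.713), 1 and 3 of 13 for exocytosis machinery (1 and 3; 0.713) and 2 and 4 of 16 for genes that beta cells normally keep silent (3 and 6; 0.429). For prohormone processing they were 1 and 1 of 7 (1 and 1; 0.713), for neural stem cell and neuronal genes 0 and 1 of 7 (0 and 1; 0.43), and for duct cell markers 1 and 2 of 6 (1 and 3; 0.488). Among duct markers Sox9 fell from 27.0 ± 2.4 to 10.4 ± 0.2 CPM (adjusted p = 1.57e-07). The lists of endocrine progenitor, alpha cell, leukocyte, endothelial and acinar genes had 4, 4, 4, 3 and 1 tested members, too few for camera; of these Myc and Sox9, both endocrine progenitor genes here, and the leukocyte gene Cd68 (-0.53) fell and 0 rose, and adjusted over the list alone 4, 0, 1, 0 and 0 fell. In the alpha, endothelial and acinar lists 0 members had an unadjusted p under 0.05 in edgeR and 0 passed in DESeq2. DESeq2 gave no adjusted p for 855 genes, which may include members of these lists. No delta or PP cell marker had enough counts to be tested, and no mitochondrially encoded gene has a row in the table. The median, the mean and the camera direction differed in sign for the lists of duct, mesenchymal, TLX target, unfolded protein response, TCA cycle, hypoxia, nuclear receptor and circadian genes.

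In all, 5 of 33 tested lists were higher and 2 lower with camera's preset correlation. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05). That setting rests on the 2 residual degrees of freedom, so little can pass it here. A list that fails it is not thereby shown to be unshifted. The fry test called 11, among them the nuclear receptor list, which holds Nr2e1 itself. The labels do not say that the libraries of a group came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Those of camera with the preset correlation compare a list's genes with the other tested genes under an assumed correlation of 0.01. They do not measure the spread between cultures either. The calls fell to 454 higher and 585 lower without TLX replicate 1, 388 and 636 without TLX replicate 2, and 355 and 484 in DESeq2. How reads shared by close copies or by overlapping genes were counted, and whether strand was used, is not given in the sources used here, so values of members of close families (Ins1 and Ins2, Ly6a, Hspa8, the Oas and Gbp families) are uncertain.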

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

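The test in this part was chosen after the table was seen. The cDNA clone rows left out of the report's comparison carried signal as well. In a fit on all 19037 feature rows with enough counts, 217 of 8020 clone rows were higher with TLX than in control and 353 were lower (edgeR, adjusted p under 0.05). At least some clone rows repeat counts of named genes, and how many do is not known, so these calls are not taken as separate evidence of change.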

How the results depend on the processing

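Nr2e1 kept its direction and call in each alternative run for it (all but glmTreat), with log2 fold changes of 5.15 to 5.29. Against 859 genes higher and 997 lower, DESeq2's Wald test gave 355 and 484 (839 in all, 837 of them among the 1856). For 855 genes, left out by its default filter on mean counts, DESeq2 gave no adjusted p. The glmTreat test against a fold of 1.5, a stricter question by construction, gave 14 and 83. Leaving out each library in turn, with the lone library assumed to vary like the other group, gave 388 to 993 higher and 585 to 1060 lower. The groups share replicate numbers, but nothing in the labels says that these pair the samples. The paired fit with a replicate block gave 1495 genes higher and 1487 lower and kept all 1856 calls; it also called Ccnd1, Ccnd2, E2f6, Mki67 and Vim higher (adjusted p of 0.001, 0.0398, 0.0424, 0.0418 and 0.028) and Cpe lower (0.0339). The differences between numbers 1 and 2 in control and TLX correlated at 0.108 across genes (0.334 over the 5503 above 32 CPM) and fell with feature length in both (Spearman rho of -0.25 in control and -0.28 in TLX across 11024 genes, which are not independent) and rose with GC content (0.361 and 0.181 across 10365 genes), tests chosen after the data were seen. In the other alternatives run both counts stayed within 1.5 times. Of the 1856 calls 0 changed direction in any alternative. That tests little, since in all 1856 both TLX libraries lay on the same side of both control libraries. Scaling moved the median log2 fold change of all genes from 0.0006 to no further than -0.0079. Gene lists higher and lower numbered 5 and 2. With an estimated correlation both became 0. In the simulated counts the single list shifted 1.32-fold was not called in this way either, so such a loss can also befall a shifted list. This setting also rests on only 2 residual degrees of freedom. How far that, or correlation between genes, caused the loss in the real lists was not tested. By fry 5 were higher and 6 lower. The E2F and Rb family was lost (fry adjusted p = 0.134). The duct, neural, p53 target and unfolded protein response lists were gained (0.0428, 0.0295, 0.0433 and 0.0428). Nuclear receptors, lower by camera without a call, were called higher (fry adjusted p = 0.0295). That list holds Nr2e1, the overexpressed gene, at a log2 fold change of 5.22, while 15 of its 24 tested members had negative values. The list was not tested without Nr2e1, so this call is no evidence on the other receptors. With genes under 10 CPM on average left out 3 lists were lower, and with single libraries left out 5 were higher each time and 2 to 3 lower. Fits without Rn45s and Lars2 or with all feature rows were chosen after the data were seen and gave 6 (extracellular matrix and adhesion gained) or 5 lists higher and 2 lower. Single libraries left out turned the direction of some genes that had not passed. Ins1 ranged from -0.025 to 0.336, Ins2 from -0.330 to 0.435 (-0.123 without control replicate 2), Pdx1 from -0.104 to 0.020, Pam from -0.104 to 0.0538, S100a4 from -0.032 to 0.172 and Mki67 from -0.00019 to 0.360. Of the other results for named genes, 1156 kept their direction and side of the threshold, 17 no longer passed and 12 newly passed. Depth limits what can be seen at 0 counts to levels above 0.302 to 0.379 CPM.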

Other observations

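The tests of losses in counting, of other cell lineages, of lost beta cell expression, of culture state and of the gene groups in the next 2 paragraphs, and the groups and genes named there, were chosen after the data were seen; the tests of trends with length, GC content and expression and of other splits were written before their results were seen.

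With camera's preset correlation, and not with an estimated one, genes induced by NF-kB and by MAP kinase signalling were lower with TLX, and chaperone and NRF2 genes were higher. These groups came to mind from genes seen to change, so they were tested over the members that were neither among the 24 genes of largest change nor in a list fixed before the data were examined. Of 19 such NF-kB targets (of 21 tested in all) 0 rose and 12 fell (adjusted p = 1.33e-09; 0.139 with an estimated correlation), and of 12 MAP kinase feedback genes (of 19) 1 rose and 9 fell (2.34e-05; 0.139). Of 20 heat shock proteins and cochaperones (of 21) 6 rose, 0 fell and 14 did not pass (0.00272; 0.139), and of 14 NRF2 targets (of 23) 5 rose and 0 fell (0.00423; 0.270). These 4 are hypotheses of a shared change, found and tested on the same libraries. Smaller changes of some members had also been seen, so the members left out remove the effect of that choice only in part. For 3 further groups no tested member was left out, so their values were computed on the genes that prompted them and test nothing: nuclear envelope and chromatin (7 of 21 rose and 1 fell; 0.000152; 0.139 with an estimated correlation), DNA repair (3 of 24 rose and 0 fell; 0.00857; 0.336) and lysosome (0 of 28 rose and 4 fell; 0.136; 0.274).

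Among single genes of these groups, Ptgs2, the inducible cyclooxygenase, fell from 516 ± 43 to 193 ± 16 CPM (SD, n = 2), the chemokine genes Ccl2 and Cxcl10 had log2 fold changes of -1.02 and -1.23, Dusp8 and Phlda1 of -1.13 and -0.90 and the growth factor genes Ereg and Hbegf of -1.08 and -0.91. Hsph1 was at 0.62, Pgd, of the pentose phosphate pathway, at 0.68, Lmnb1 at 0.85, Ncapd2 at 0.57 and Msh6 at 0.75.

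In libraries labelled MIN6, 14 of 25 beta cell function genes had 0 counts throughout and 3 reached 5 CPM. The pattern is common to control and TLX, so no explanation by TLX was tested, and a loss of whole genes in counting is argued against by 0 of 124 ribosomal protein, oxidative phosphorylation and TCA cycle genes at 0 in all 4 libraries. Cells of another line or origin may be a candidate explanation: of the mesenchymal and fibroblast list, fixed before the data were examined, 55% of genes reached 5 CPM, against 28.6% of alpha cell, 26.7% of duct, 25% of leukocyte, 16.7% of adipocyte, Schwann cell and osteoblast, 8.33% of melanocyte, myoblast, keratinocyte and simple epithelial and 0% of acinar, endothelial and hepatocyte markers; 13 of 24 exocytosis genes and 7 of 18 genes of prohormone processing and secretory granules, with Pam at 87.4 and Cpe at 75.4 CPM, also did, as did 16 of 22 genes that beta cells normally keep silent. No share over all gene rows was worked out at 5 CPM, but 8556 of 23473 passed the filter of 10 CPM on average. Such levels were thus common, which weakens the 55% and the count of silent genes as marks of another lineage. Many cultured lines also express collagen and vimentin, so the comparison of lists does not tell another line from MIN6 cells that lost beta cell expression. Chosen after their values were seen, Ptprn of the granule list averaged 91.4 CPM and Pax6 of the beta cell transcription factor list 13.8 CPM. In these lists 7 of 18 and 13 of 23 genes had 0 counts in all 4 libraries. Ins1, at 70 to 98 counts per library, Ins2, at 32 to 50, and Pdx1, at 33 to 40, were low but present. Reads shared by close copies leave the values of Ins1 and Ins2 uncertain, and stray reads were not tested for. The bearing of these low counts on origin is therefore uncertain. Another line and MIN6 cells that lost beta cell expression both stay open.

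Immediate early and ATF4 genes were lower and G2/M genes higher with TLX. A trend with transcript length, GC content or expression as the whole cause is argued against by the medians after removing such trends. They were -0.60 (95% bootstrap interval -0.82 to -0.40, -0.62 before), -0.39 (-0.47 to -0.25, -0.39 before) and 0.36 (0.32 to 0.41, 0.35 before). The intervals resampled the genes of each list, which may change together, and not the libraries. They therefore leave out the spread between libraries. A difference in culture state at harvest, or between the stable lines apart from TLX, cannot be told apart from TLX itself: libraries of a group differed by at most 0.026 in the median log2 level of the immediate early genes and the groups by 0.562, but each group may be a single line. An effect of TLX stays open and untested. Among the 3 ways to split the 4 libraries into pairs, the real split called 1856 genes and the highest of the others 0, and so few splits allow no share under 0.05 (1 of 3 reached the real count).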
